A study of Drosophila melanogaster with 2 samples.

How the data were processed

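The data came from chromatin immunoprecipitation followed by sequencing (ChIP-seq) of whole Drosophila melanogaster embryos of both sexes, collected 0 to 24 h after egg laying. The embryos carried an eGFP exon inserted in an intron of Hmx, a gene for a homeodomain transcription factor, so that Hmx protein was made as a fusion with eGFP. Per the labels' protocols, chromatin was fragmented by sonication, a size range of 200 to 800 was recorded without a unit, and the fusion protein was pulled down with an antibody against GFP. The antibody field of the labels names Hmx itself, whereas the sample description names GFP. The 2 samples, numbered replicate 2 and replicate 3 by the labels as biological replicates, formed 1 group. The control alignment against which the regions were called was not analysed here, so no level in untagged embryos can be set beside the values.

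The authors deposited region lists and no counts of reads, so the number of reads behind each list is unknown and sequencing depth gives no interval. For each of the genome builds dm6 and dm3 the files held a list of 30000 regions per replicate. Another list of 30000 regions came from both replicates pooled. The pooled list was labelled as peaks and background used as input to the irreproducible discovery rate (IDR) procedure. Its weaker regions may therefore be background and are not taken as called binding. A further list was named as the optimal set passing the IDR procedure. Per the file records, each list was made against the control alignment, the IDR set was derived from the pooled list and both replicates' lists, and the caller, the aligner and the IDR threshold are not given in the sources used here. Each region carried a signal value on the caller's own scale, which the authors deposited. This value was used to rank and describe regions within a list and was correlated between the replicates. On each build the mitochondrial values were also set against the nuclear median. Regions also carried a −log10 q value that the authors deposited. In the dm6 pooled list its highest value was 2.18, a q value of 0.653%, and 1608 regions shared it, so it could not rank the strong regions.

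Regions were sorted by the deposited signal. The 1607 regions of the dm6 IDR set were the 1607 strongest regions of the pooled list, with unchanged coordinates and signal. Analyses of genome position, genes and sequence used the 1595 IDR regions on chromosome arms 2L, 2R, 3L, 3R, 4 and X, and left out the 12 regions on the mitochondrial genome, a choice made after the data were seen. Coordinates are 1-based on dm6. Genes came from Ensembl release 115, annotation BDGP6.54, without transposable elements, and sequence from the RefSeq copy of that assembly. All 7 sequences used were long enough for every dm6 region and gene. A dm3 genome was not used here, so dm3 regions were only counted, ranked and compared with each other.

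Overlap between replicates was taken over the 1607 strongest regions of each, at 1 bp or more, with bedtools 2.31.1, mitochondrial regions included, and chance from 1000 shuffles of the nuclear replicate 2 regions within their arms. Signal was correlated over nuclear IDR peaks whose summit lay within 250 bp of a summit of each replicate. Correlation intervals came from 1000 bootstrap draws over peaks. Peaks are not independent replicates. Promoter summits lay within 500 bp of an annotated transcription start, and their share was compared with 1000 shuffles of the summits within their arms, leaving out runs of N, by a 2-sided permutation p. Shares of single lists have 95% Wilson intervals, which cover counting error only.

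For genes, 27 lists were fixed before the data were examined, covering homeobox, neural, patterning, signalling, tissue, stress, germline, ribosomal, proteasome, chorion, chemoreceptor and odorant-binding genes. The lists held 333 symbols and families matched by symbol. All symbols were found, 10 of them under a current name. A gene counted as bound when an IDR summit fell in its body or 1 kb upstream. Bound members were compared with 10000 random lists of protein-coding genes matched in 20 bins of locus length, 2-sided, with Benjamini-Hochberg adjustment over the lists and calls at an adjusted p of 0.05 or less. Every 6-mer, taken with its reverse complement, and the 8-base DRE motif were compared between the 50 bp either side of each summit and a window of equal width centred 300 bp to the left or right. The test was an exact 2-sided binomial test of the peaks with the motif in only one window, adjusted over 2081 motifs. Because the windows differed in base composition, a second background was added after seeing the data. It consisted of 20 draws of random windows with the same number of G and C letters, on the same side of 500 bp from a start and over 1 kb from any summit of the set tested. The draws share the same summits, so they are not independent tests. Arms were compared with their share of non-N bases by exact 2-sided binomial tests with Benjamini-Hochberg adjustment.

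On simulated data with 1595 random summits, 0 gene lists and 0 motifs were called. These summits were drawn evenly over the arms. They lacked the base composition, promoter share and nearness to each other of the real summits, so false calls from these were not tested. A 6-mer planted in 163 simulated peaks was called and ranked 1 by p, with 4 other 6-mers called, and in 303 peaks with 9 others. Both of the gene lists that received planted summits were called with 0 other lists. These had 12 of 15 gap and pair-rule genes and 31 of 85 ribosomal protein genes bound, so weaker effects were not simulated. Alternatives fixed before the data were examined changed the overlap rule, the number of top regions, the matching distance, the build, the promoter window, the assignment of genes, the length matching, the motif window and the flank distance. They also took the stronger part of the IDR set, or the strongest regions of each replicate alone in place of the IDR set.

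Genes were named by a rule fixed in advance. The rule took the genes at the 15 strongest IDR peaks, the 10 protein-coding genes with most IDR summits, and up to 3 members with the strongest peaks of each called list and of the NK-class and Hox lists. It also took Hmx, the 10 6-mers with the smallest adjusted p, and 10 motifs listed beforehand. Since 12 of the 15 strongest peaks were mitochondrial, the 15 strongest nuclear peaks were named as well, after their values were seen. Members of lists that passed no test, where named, were also chosen after their values were seen. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.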

Results

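The naming of the 15 strongest nuclear peaks, the promoter share of weaker pooled regions, the places of summits outside promoters, the overlap of nuclear regions alone, the share of weaker regions on chromosome 4, the G+C content of weaker regions and of all starts, and the windows matched on composition were chosen only after the result was seen. Hmx-eGFP was mapped in 2 biological replicates of whole embryos of 0 to 24 h, which formed 1 group with no second condition. The comparisons are therefore between the replicates, between bound and shuffled positions, between gene lists and length-matched genes, and between summit and neighbouring sequence. The dm6 IDR set held 1607 regions, of which 1595 lay on the chromosome arms and 12 on the mitochondrial genome. Nuclear signal values ran from 78.4 to 1041 with a median of 110.5. At a q value below 5%, the pooled list held 3184 of its 30000 regions, the replicate 2 list 4619 and the replicate 3 list 2050. The dm3 IDR set, made from the same libraries, held 1629 regions, 2 of them mitochondrial.

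The strongest nuclear peak, on 3L at 19590435 to 19590813, had its summit 107 bp from the start of CG14100, with a signal of 1041. It was also the strongest nuclear region of either replicate alone. A peak on 2L at 480915 to 481271 lay in an intron of ush, which encodes a zinc-finger cofactor of GATA factors, with a signal of 967.5. It was 1396 bp from the start of the neighbouring gene cbt. A peak in an intron of CG11050 had a signal of 866.9. Genes of the mitochondrial ribosome stood at 3 of the 15 strongest nuclear peaks. These were mRpS10, which shares its upstream region with the arginine methyltransferase gene Art3 (signal 743.5, 3R 15229358 to 15229712), mRpL41 with CG8079 (714.4) and mRpS23 with CenG1A (658.0).

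The other strong nuclear peaks lay at Ugalt, a UDP-galactose transporter gene, with eIF2Bbeta (807.5), at Lk6, a kinase of the translation factor eIF4E (665.5), and at Chro, which encodes the chromatin protein Chromator, with the TFIIH subunit gene Ssl1 (652.6). Further peaks lay at ph-p, a Polycomb group gene (648.8), CG31145 (607.3), the non-coding genes lncRNA:Vinr and lncRNA:CR44619 (593.2), CG1888 (566.2), PNPase with Gprk2 (545.3) and SLC5A11 with CG8419 (544.8). Of the 15 summits, 12 were within 500 bp of a transcription start, and those at ush, CG11050 and Lk6 were intronic and farther away.

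Of the genes with most IDR summits, the forkhead gene CHES-1-like had 9 summits in a locus of 28.0 kb, and shn, a zinc-finger gene of the BMP pathway, had 7 in 59.3 kb. There were 6 summits each at the co-repressor gene sbb, at CG14434 and at the nuclear receptor gene Hr4. Raf, the Notch coactivator gene mam, the bHLH gene crp and the cell adhesion gene kirre had 5 each, kirre in a locus of 395.1 kb. Trl, which encodes GAGA factor, had 4 summits in 14.1 kb, the strongest of them with a signal of 530.8 in an intron at 3L 14759349 to 14759693. Other genes, Rtnl1 among them, also had 4, and Trl was taken for its stronger peak. In all, 1700 of 13945 protein-coding genes, or 12.2%, had an IDR summit in the body or 1 kb upstream.

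The replicates shared most of their strongest regions. Of the 1607 strongest regions of replicate 2, 1076 overlapped one of the 1607 strongest of replicate 3, a share of 67.0% (95% Wilson interval 64.6 to 69.2%). Without the 16 mitochondrial regions of replicate 2 it was 1072 of 1591, or 67.4%. Shuffled nuclear regions overlapped in 0.973% on average and in 1.82% at most (permutation p = 0.0020, 2-sided, the smallest that 1000 shuffles can give). Of the 1595 nuclear IDR peaks, 1547 had a summit of each replicate within 250 bp. The IDR set was itself derived from both replicates' lists, so this matching was partly built in. It is no separate evidence of agreement, and the correlation below holds for peaks selected in this way. Across these peaks, which are not independent replicates, signal values correlated with a Spearman rho of 0.610 (bootstrap interval 0.571 to 0.647) and a Pearson r of 0.726 on the log10 scale.

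**Figure D1:**
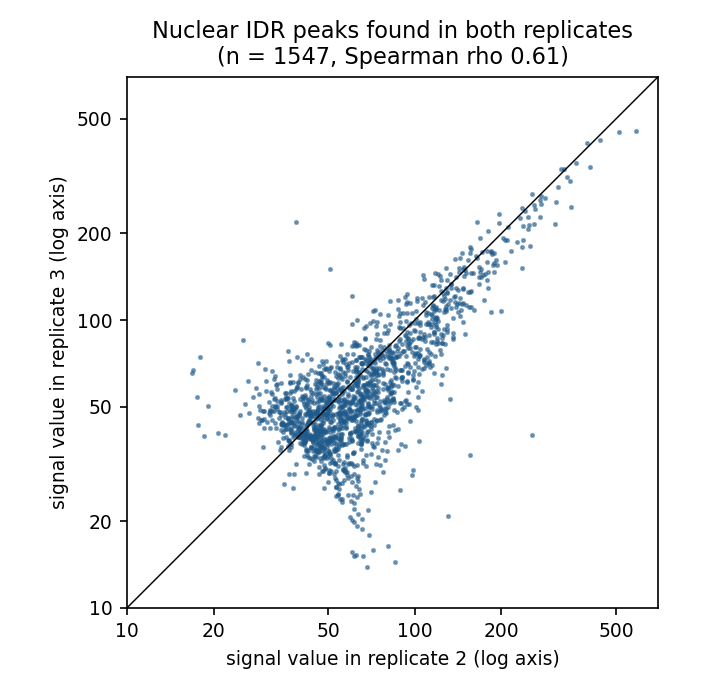
Signal value of each nuclear IDR peak in replicate 2 (horizontal, log axis) and replicate 3 (vertical, log axis), on the caller's scale, with a line at equal values. Each point is 1 of 1547 peaks matched in both replicates, and the Spearman rho was 0.610.

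Most Hmx-eGFP summits lay at promoters as defined by 500 bp, while 44.8% lay within 250 bp of a start. Of 1595 nuclear IDR summits, 958 were within 500 bp of an annotated start, a share of 60.1% (95% Wilson interval 57.6 to 62.4%). Shuffled summits gave 13.6% ± 0.840 (SD of 1000 shuffles), so the share was 4.40 times that of shuffled positions (permutation p = 0.0020, the smallest possible). In every shuffle positions could fall on any base other than N. Whether regions could be called at all of these bases was not examined. For 93.2% of these promoter summits the nearest start belonged to a protein-coding gene. Introns held 28.7% of all summits (39.3% of shuffled ones), intergenic sequence 8.53% (27.3%), 3′ UTRs 1.07% (4.42%) and coding exons 0.125% (13.8%), each with an adjusted permutation p of 0.0028 over 7 classes, and 5′ UTRs and non-coding exons were not called (0.294 and 0.456). The 7 shares sum to the whole, so the rise at promoters lowers the others. Among the 637 summits outside promoters, set against shuffled positions outside promoters, introns held more (71.9% against 45.9%) and so did non-coding exons (2.51% against 0.938%). Intergenic sequence (21.4% against 31.2%), 3′ UTRs (2.67% against 5.18%) and coding exons (2 summits, at otp and CG10357, 0.314% against 15.9%) held fewer. The adjusted permutation p was 0.0048 for 3′ UTRs and 0.0030 for the other 4 classes, and 5′ UTRs were not called (0.496). Regions of the pooled list outside the IDR set, which may include background, had 21.2% of summits at promoters. In this comparison, chosen after seeing the data, the IDR share was 2.83 times theirs.

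**Figure D2:**
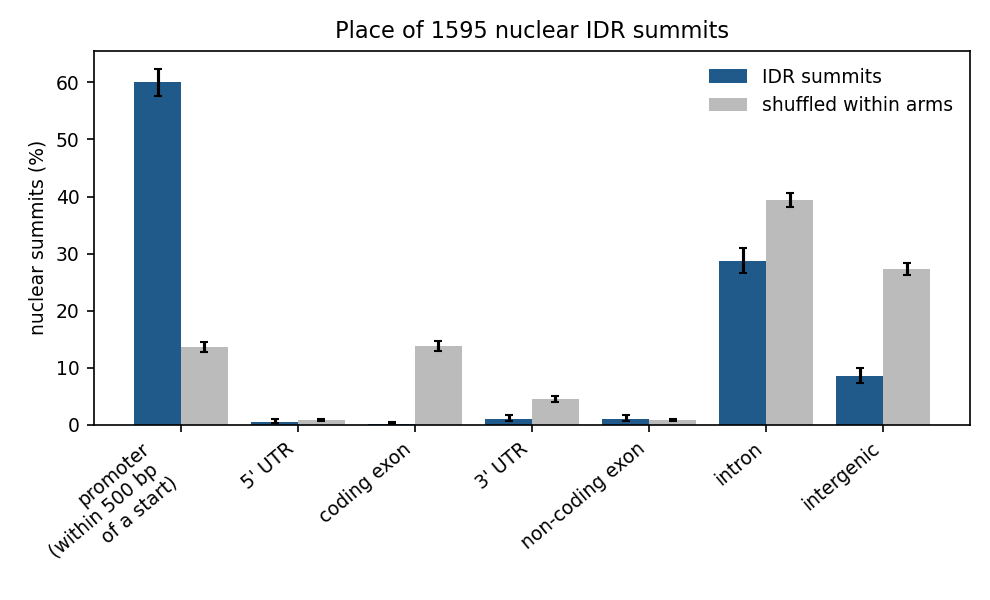
Share of nuclear summits (vertical, percent) in each class of annotation, for the IDR set (blue, error bars 95% Wilson intervals) and for 1000 shuffles within the arms (grey, mean and SD). Promoters held 60.1% of IDR summits against 13.6% of shuffled ones, and coding exons 0.125% against 13.8%.

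Promoter summits sat upstream of the start. Of 915 summits within 500 bp of a protein-coding start, 793 were upstream of it, or 86.7% (95% Wilson interval 84.3 to 88.7%). The median place was 135 bp upstream, with quartiles of 69 and 232 bp.

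Genes for cytoplasmic ribosomal proteins were bound more often than length-matched genes. Of 85 members, 26 had an IDR summit, against 7.05 expected (95% of random lists 3 to 12, adjusted permutation p = 0.0027, the raw permutation p of 0.0002 being the smallest possible). The 26 genes took 27 summits, and 25 genes had a summit within 500 bp of their own start. RpL34b had its strongest peak 101 bp upstream of the start (3R 9401109 to 9401544, signal 222.8), RpL32 216 bp upstream (3R 30046290 to 30046401, 207.5) and RpS27 30 bp upstream (3R 25247457 to 25247595, 204.5). With genes assigned by nearest start 17 of the 85 were bound against 5.20 expected (adjusted permutation p = 0.0027). This was the only list of 27 called higher. Here and below, the random genes were matched on length only. Expression and chromatin accessibility were not measured here, so a difference in these cannot be told apart from a preference of Hmx-eGFP. The proteasome list had 4 of 48 members bound against 4.02 expected (adjusted permutation p = 1), which were Rpn5 (signal 185.8), Rpn13 (96.8), Rpn11 (90.0) and Prosalpha7 (80.2). Like the members of other uncalled lists below, these were named after their values were seen. With replicate 3 alone 2 of 48 were bound.

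Chemoreceptor genes, which serve smell and taste, were bound less often than length-matched genes, with 0 of 179 members against 17.96 expected (adjusted permutation p = 0.0027). Homeobox genes other than the NK-class and Hox genes were also bound less often, with 2 of 54 members against 11.3 expected (adjusted permutation p = 0.0036). The bound members were otp, with a summit in a coding exon (2R 20884352 to 20884787, signal 149.2), and ct, with a summit in an intron (X 7618197 to 7618632, 113.9). The homeobox call was lost with the strongest regions of replicate 3 alone (4 members bound, adjusted permutation p = 0.069), kept with replicate 2 alone (1 member, 0.0018), and lost with the stronger part of the IDR set (0.495), with genes assigned by nearest start (0.127) and without length matching (0.222). The ratio of 0.177 rose to 0.346, 0.311, 0.331 and 0.303 in the 4 settings that lost the call and so stayed below 1.

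The NK-class homeobox list, to which genes related to Hmx belong, had 1 of 12 members bound against 2.50 expected (adjusted permutation p = 1). That member was NK7.1, with a summit 417 bp upstream of the start (3R 14373150 to 14373585, signal 141.7). Of 8 Hox genes, Antp had a summit in an intron (3R 6912246 to 6912681, signal 108.7), against 2.11 genes expected (adjusted permutation p = 1). No gap or pair-rule gene was bound (0 of 15, 1.94 expected, adjusted permutation p = 0.624).

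Lists of neural genes were not called against length-matched genes. Bound members were 2 of 19 proneural and neuroblast genes (brat, insc), 1 of 11 Enhancer of split genes (E(spl)m3-HLH) and 1 of 7 temporal genes of neuroblasts (grh). Of 20 genes of neuronal differentiation 2 were bound (elav, with a signal of 267.2, and ChAT), of 12 glial genes 3 (moody, pnt, Gs2) and of 20 axon guidance genes 4 (unc-5, dlp, Fas3, fra). These 6 lists had adjusted permutation p values from 0.564 to 1. With replicate 3 alone 9 of the 20 axon guidance genes were bound (1.62 times the expected number in place of 0.765, adjusted permutation p = 0.443), and with replicate 2 alone 1 proneural gene was. Signalling lists without a call were BMP (4 of 13, Dad with a signal of 251.9, shn, brk and sog), Notch (3 of 10, mam, N and neur), Wnt (3 of 15, arr, fz2 and fz), Hedgehog (1 of 11, dally) and ecdysone response (6 of 13, including Hr3 with a signal of 322.4). The ecdysone ratio of 1.81 was 0.994 with summits within 1 kb of a start (2 bound) and 2.75 with the stronger part of the IDR set (5 bound), and neither was called (adjusted permutation p = 1 and 0.398). Tissue lists without a call were muscle and mesoderm (3 of 18, kirre, sls and Mef2), germline (1 of 10, vas), and gut and endoderm (1 of 8, bowl with a signal of 247.3). With replicate 3 alone the BMP list had 7 members bound (2.72 times the expected number in place of 1.60, adjusted permutation p = 0.069), the gut list 2 and the germline list 0, and with replicate 2 alone the germline list had 2. The fat body and yolk list and the chorion list had 0 of 9 members bound each, and the odorant-binding proteins 0 of 51 (3.11 expected, adjusted permutation p = 0.292).

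Trachea and epithelium, heat shock and EGFR lists had the next lowest adjusted p and were not called. Of 11 tracheal and epithelial genes, 7 were bound against 2.59 expected (adjusted permutation p = 0.058), among them baz, rib and dlg1. With genes assigned by nearest start this list was called (adjusted permutation p = 0.025). The ratio of 2.70 was 1.83 with replicate 3 alone, 1.94 with replicate 2 alone (5 bound each), 2.42 with summits within 1 kb of a start (4 bound) and 1.38 with the stronger part of the IDR set (2 bound), with adjusted permutation p from 0.540 to 1. The heat shock list had 5 of 13 bound against 1.36 expected (adjusted permutation p = 0.076), namely Hsp26, Hsp83, the overlapping genes Hsp22 and CG4456, which share 1 summit, and Hsp27, with a summit 129 bp upstream (signal 186.6). With the stronger part of the IDR set 2 were bound (adjusted permutation p = 1), and with replicate 2 alone 4 (0.422). The EGFR list had 7 of 13 bound against 2.82 expected (adjusted permutation p = 0.093), including the ligand gene spi (251.2) and the antagonist gene aos (194.4). With the stronger part of the IDR set 2 were bound, and the ratio fell from 2.48 to 1.23 (adjusted permutation p = 1). Without length matching the tracheal (adjusted permutation p = 0.0054), EGFR (0.0097) and ecdysone lists (0.0234) were called higher and the odorant-binding list lower (0.0097).

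**Figure D3:**
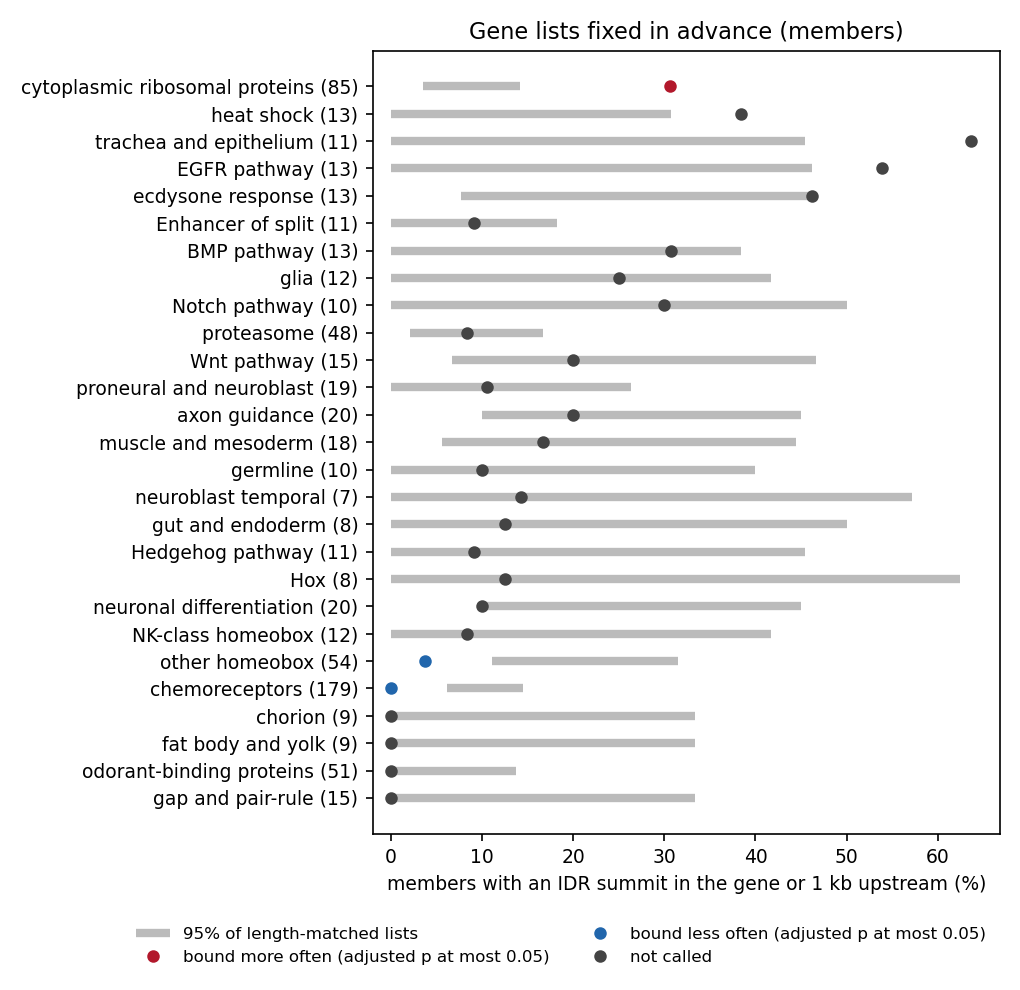
Percent of the members of each list (size in brackets) with an IDR summit in the gene or 1 kb upstream (horizontal, points), with grey bars holding 95% of length-matched random lists. Cytoplasmic ribosomal proteins (30.6%) lie to the right of their bar, and chemoreceptors (0 of 179) and other homeobox genes (3.70%) to the left of theirs. The trachea and epithelium (63.6%), EGFR (53.8%) and heat shock (38.5%) lists also lie to the right of their bars but were not called after adjustment.

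No IDR peak lay at the Hmx gene itself, at 3R 17558930 to 17569097, or within 5 kb of it. The pooled list held 5 weaker regions there, the strongest at 17561200 to 17561635 with a signal of 44.2 and rank 6171 of 30000. In replicate 2 the strongest of 4 regions ranked 14040 (signal 17.5), and in replicate 3 the strongest of 8 ranked 4371 (27.9). How many of 30000 regions would fall in such a window by chance was not computed. These regions may be background and do not show binding at Hmx.

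Summits were richer in A and T than the sequence beside them. The 101-bp windows at the summits had a G+C content of 31.1%, against 44.1% in the flanks and 42.2% over all arms. The decrease was 12.95 percentage points (bootstrap interval 12.3 to 13.6). With flank sides drawn anew it was 12.95 at summits within 500 bp of a start and 12.4 farther away. Windows at the median distance of 135 bp upstream of all 19252 protein-coding starts had 37.6%. Weaker regions also had lower G+C at the summit, by 5.70 points at ranks 20001 to 30000 of the pooled list.

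**Figure D4:**
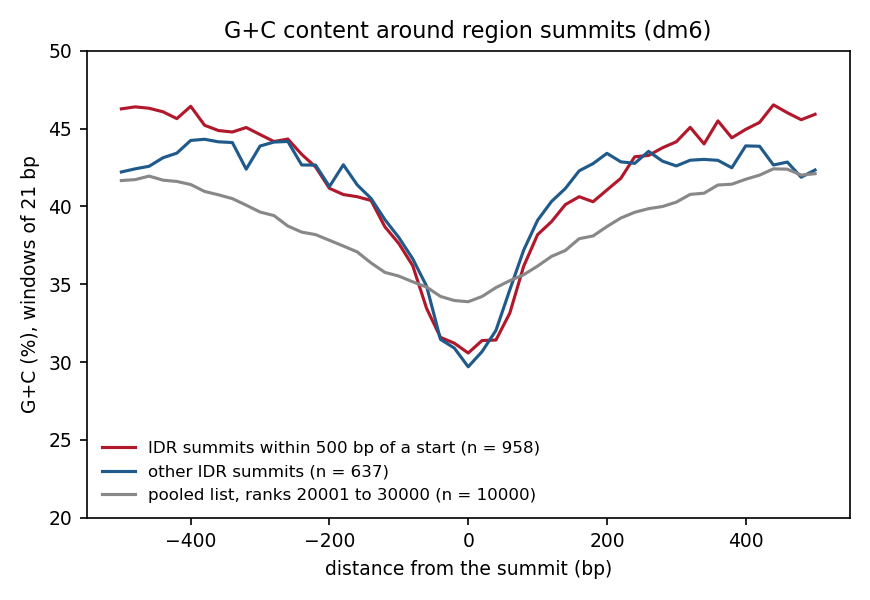
G+C content (vertical, percent, windows of 21 bp) against distance from the summit (horizontal, bp) on dm6, averaged over IDR summits within 500 bp of a start (red, 958), other IDR summits (blue, 637) and the 10000 weakest pooled regions (grey). All of them have their lowest values at the summit.

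Of 2081 motifs, 363 were in more peaks at the summit than in the flank and 819 in fewer (exact binomial tests, adjusted p of 0.05 or less). The 10 with the smallest p held only A and T. They were TTAAAA (634 against 223 peaks, ratio 2.84), ATTTAA (2.97), AAAATA (2.33), ATTTTA (2.81), TAAAAA (2.37), TTTAAA (3.40), AAATAT (2.48), AAAAAT (2.11), AAATAA (2.24) and ATTAAA (2.54). The median ratio decreased with every added G or C, from 2.38 for the 36 6-mers without either to 0.186 for the 36 made only of them. The highest ratio among the called 6-mers was that of TAGTAA, in 141 summits against 35 flanks (4.03).

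Among the homeodomain sites, TAATTA was in 179 summits against 85 flanks (ratio 2.11, exact binomial test, adjusted p = 1.0e-08) and TAATTG in 194 against 135 (1.44, adjusted p = 0.0024). Both ratios were below the median of 6-mers with as many G and C letters, which was 2.38 and 1.96. TAAGTG was not called in the exact test (1.18, adjusted p = 0.407), and CAAGTG was in fewer summits than flanks (0.552, adjusted p = 0.00022). The GAGA factor site GAGAGA (0.398, adjusted p = 2.0e-08), the E-box CAGCTG (0.453, adjusted p = 0.00011) and the palindrome CTCGAG (0.333, adjusted p = 0.015) were in fewer summits, whereas the Zelda site CAGGTA (0.714, adjusted p = 0.261), the E-box CATATG (1.27, adjusted p = 0.282) and the DRE motif TATCGATA (2.22, adjusted p = 0.084) did not pass the exact test. The call of CAAGTG was lost with 25 bp either side (ratio 0.568, exact test, adjusted p = 0.070) and with the stronger part of the IDR set (ratio 0.644, 0.068), where fewer windows held it. That of CTCGAG was lost with these (ratios 0.5 and 0.455, exact test, adjusted p = 0.359 and 0.317) and with replicate 3 alone (0.444, adjusted p = 0.122). TATCGATA was called with 100 bp either side (ratio 2.5, exact test, adjusted p = 0.00083), a flank at 600 bp (10, 0.00041, with few flanks holding it) or replicate 2 alone (2.60, 0.022). Its ratio fell to 1.00 with replicate 3 alone, however, and the excess was also nearly lost with the stronger part (exact test, adjusted p = 1 for both). CATATG was called with replicate 2 alone (exact test, adjusted p = 0.027). GAGAGA and CAGCTG stayed called lower in each planned setting. Their ratios ran from 0.338 and 0.333 with the stronger part to 0.646 and 0.719 with 100 bp either side.

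Against random windows of the same G+C content, most of these differences were lost and ACAGTG stood out. Over 20 draws, added after seeing the data, a median of 1 motif of 2081 was called (range 0 to 8). ACAGTG, with its reverse complement CACTGT, was called higher in 14 of the 20 draws, and no other motif in more than 5. It was in 101 summits, or 6.33%, and in 3.09% of matched windows, a ratio of 2.05 (95% Wilson interval of the summit share over the matched mean, 1.70 to 2.47). Against the flanks its ratio was 1.44 (exact binomial test, adjusted p = 0.034). It was called in 20 draws with replicate 3 alone (ratio 2.38), in 10 with replicate 2 alone (1.98) and in 0 with the stronger part of the IDR set (44 peaks, ratio 1.83). The motif was picked out of 2081 after the draws were seen, and the draws share the same summits. CTGTGC was called higher in 5 draws, with a ratio of 1.99, and its reverse complement GCACAG shares ACAG with ACAGTG. CAGTGC, called higher in 2 draws (1.75), shares CAGTG with it. ACTGTG, CACTGC and CAGTGG, called higher in 1 draw each, also overlap it, directly or as reverse complements. Whether these are parts of 1 longer sequence was not tested. TATATA was called lower in 3 draws (0.744). TAGTAA had a ratio of 1.21 (interval 1.04 to 1.42) and was called in 0 draws. At least 1 of the 4 homeodomain sites was in 29.3% of summits and in 31.1% of matched windows, a ratio of 0.945 (interval 0.874 to 1.02). The ratios of GAGAGA and CAGCTG, below 1 against the flanks, were 1.24 (interval 0.947 to 1.62) and 1.204 (0.883 to 1.64) against matched windows, and neither was called in any draw. TATCGATA was in 1.25% of summits and 0.658% of matched windows (ratio 1.90, interval 1.24 to 2.93, 20 peaks) and was called in 0 of the draws. Its ratio was 1.07 (interval 0.492 to 2.32) with the stronger part, 1.56 (0.962 to 2.53) with replicate 3 alone and 2.28 (1.56 to 3.33) with replicate 2 alone.

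**Figure D5:**
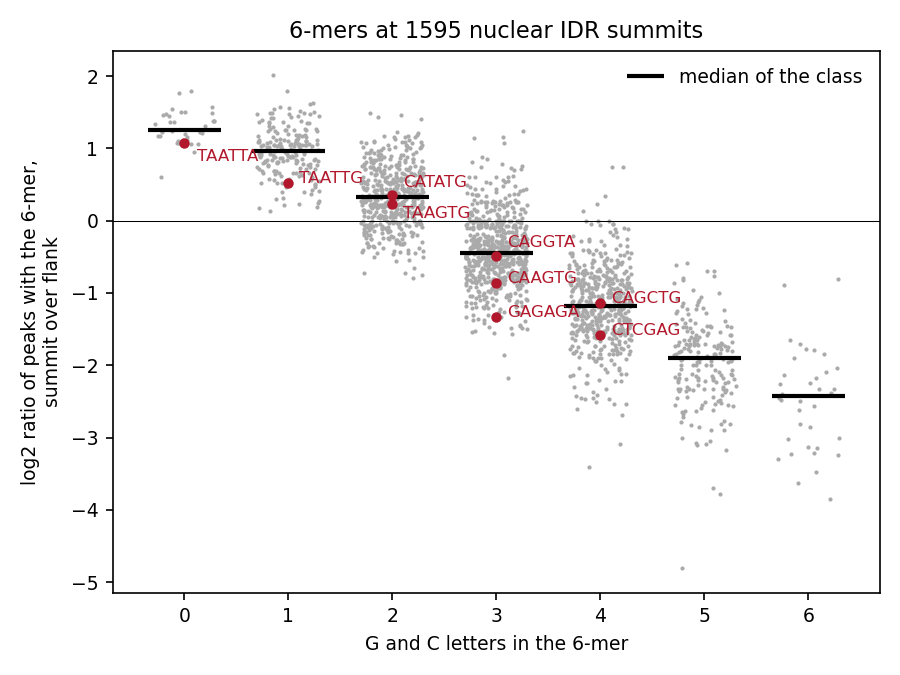
Log2 ratio of the number of peaks with a 6-mer at the summit over the flank (vertical) against the number of G and C letters in the 6-mer (horizontal), over 1595 nuclear IDR peaks, with 6-mers in grey, class medians as black bars and the motifs listed in advance in red. Ratios decrease with G and C letters, and TAATTA and TAATTG lie below their class medians.

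The X held 279 of 1595 peaks, or 17.5% (95% Wilson interval 15.7 to 19.4%), against 17.6% of bases (exact binomial test, adjusted p = 0.974). Chromosome 4 held 6 peaks, or 0.376%, against 0.996% of bases (exact binomial test, adjusted p = 0.046). Over all listed regions its share was instead above that of bases, with 760 of the 30000 pooled regions, or 2.53%, 2.64% in the replicate 2 list and 2.20% in that of replicate 3, shares that were not tested. In the stronger part of the IDR set the ratio to the share of bases stayed at 0.381 against 0.378, but with 3 peaks it was not called (exact test, adjusted p = 0.270). With replicate 3 alone and replicate 2 alone the ratio itself rose to 0.689 and 0.631 (exact test, adjusted p = 0.585 and 0.491). The other arms had adjusted exact-test p values from 0.428 to 0.747.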

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

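All tests of the mitochondrial regions were chosen after the result was seen. In the dm6 IDR set 12 regions lay on the mitochondrial genome, which the comparisons above left out apart from the overlap of the replicates' strongest regions, and they are described here for that reason alone. They were 12 summits in 6 distinct intervals, took ranks 1 to 12 with signal values of 3206 to 23788, and the intervals overlapped mt:CoI, mt:CoII, mt:ATPase6, mt:CoIII, mt:ND5, mt:ND4, mt:ND6 and mt:Cyt-b. The highest was 215.2 times the nuclear median on dm6 and 2.17 times on dm3, where 2 regions ranked 149 and 166. The builds differed 99.3-fold although both start from the same libraries. A control or a handling of mitochondrial reads that differs between the builds could give such a gap. The comparison therefore cannot decide whether the immunoprecipitate held an excess of mitochondrial DNA. Both replicates had such regions on dm6, 16 in replicate 2 and 4 in replicate 3, so a single replicate did not carry them. The control alignments and the handling of the mitochondrial sequence on each build stay open, untested, and no biological explanation was tested.

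The dm3 pooled list held 319 regions on unplaced or heterochromatic sequences, which no comparison used. The strongest ranked 2928 with a signal of 59.6, and 0 were in the dm3 IDR set.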

How the results depend on the processing

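The alternatives were fixed before the data were examined, except the composition-matched windows and the weaker pooled regions as promoter background. Of 35 alternative values of the main results, 31 kept their direction and their side of the threshold, stayed within the stated interval, or for counts within 1.5 times. The Spearman rho rose to 0.685 over the stronger part of the IDR peaks, and the cause was not tested. Called gene lists rose from 3 to 6 without length matching, which compares long genes with short ones. The 6-mer calls decreased from 1182 to 785 with 25 bp either side, where shorter windows hold fewer motifs, and to a median of 1 with windows matched on composition. Under the other motif settings 837 to 1340 were called, and no motif called in both the main and a planned setting changed direction. The promoter ratio ran from 2.83 to 5.93 and the share of regions common to the replicates from 57.8 to 72.9%. With the strongest regions of either replicate alone the promoter ratio was 4.13 to 4.64, the list calls 2 to 3, the 6-mer calls 1122 to 1193, the X share 16.7 to 17.7% and the peaks at Hmx 0.

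For the 7 lists called under at least 1 setting, the 10 listed motifs and chromosome 4, 116 alternative values were compared. Of these, 89 were called or uncalled as in the main setting, many uncalled in both, 18 lost a call and 9 gained one. There were 0 calls in the opposite direction. In the first draw of matched windows TAATTG (0.851), TAATTA (0.989), CAAGTG (1.05), GAGAGA (1.21) and CAGCTG (1.63) crossed a ratio of 1 uncalled, and count as lost. The dm3 share of chromosome 4 was not tested and was judged by the main interval. The ribosomal protein and chemoreceptor calls held under each of the 6 alternatives, with adjusted p from 0.0018 to 0.0027. Leaving out a replicate was not possible for the overlap and the correlation, which need both, and a dm3 expectation per arm was not computed because a dm3 genome was not used here. Depth is unknown, so the lack of an IDR peak at a gene says only that none passed the procedure in these libraries.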

Other observations

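The tests of mitochondrial ribosomal genes and divergent genes, the windows matched on composition, the weakest regions, TAGTAA and the second background for neighbouring peaks were chosen only after the result was seen. Nuclear genes of the mitochondrial ribosome, a list added after 3 of them were seen at the 15 strongest nuclear peaks, had 13 of 73 members bound against 4.61 expected from length-matched genes (permutation p = 0.0008). Beside mRpS10, mRpL41 and mRpS23, these included mRpL23 (signal 395.3), mRpL24 (176.6) and mRpL34 (126.7). Without the 3 that prompted the test, 10 of 70 were bound against 4.43 expected (ratio 2.26, permutation p = 0.023, neither p adjusted), so binding near these genes may extend past the strongest peaks. For those 70 genes the ratio was 2.42 with replicate 2 alone (11 bound, permutation p = 0.0090), but the test was not passed with replicate 3 alone (8 bound, ratio 1.96, permutation p = 0.0998) or with the stronger part of the IDR set (4 bound, ratio 1.74, permutation p = 0.390). An assignment by nearest start was not made for this list. Some of the summits may belong to a neighbouring gene, as that at mRpL27 was also counted for RpL27A (signal 102.0). Promoters between divergent genes were also common. Of 915 promoter summits, 345 or 37.7% lay within 500 bp upstream of starts on both strands, against 17.6% on average and 21.7% at most in 1000 draws that placed the same distances at random starts (permutation p = 0.0020, the smallest possible). The draws took any of the 19252 protein-coding starts, alternative starts of a gene included. They were not matched by gene or arm, which may lower this background.

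IDR peaks lay near each other more often than shuffled ones, in a test planned before the data were examined. Another IDR summit was 500 bp to 5 kb away for 31.4% of peaks, against 10.2% on average and 13.6% at most in 1000 shuffles (permutation p = 0.0020, the smallest possible). When promoter summits were instead moved to random starts, a background added later, the mean was 13.1% and the highest value 17.6%.

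For the sequence at the summits, a preference of Hmx-eGFP for homeodomain sites, the biological explanation, met its planned condition against the flanks through TAATTA (ratio 2.11). Because the flanks hold more G+C, that test was replaced by matched windows, where the 4 sites had a ratio of 0.945, with an upper bound of 1.02 below the 1.5 set in advance for the flanks, which argues against these sites as the source of the pattern, while forms longer or looser than a 6-mer were not tested. For GAGA factor and Zelda sites the flank ratios of 0.398 and 0.714 met the planned condition against them, but the flanks hold more G+C. Against matched windows either site was in 5.08% of summits, 1.16 times the matched share. Its upper bound of 1.43 lay below the 1.5 set for a cause but above the bound set in advance for none. GAGAGA alone had a ratio of 1.24 with an upper bound of 1.62. The matched windows therefore cannot decide on a small excess of these sites.

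Base composition could account for most of the 6-mer differences. The planned test named the most enriched 6-mer, which can be read in more ways than 1. For TTAAAA, with the smallest p, the median ratio of 6-mers with as many G and C letters was 0.836 of its own, above the bound of 0.8 set in advance, but for TAGTAA, with the highest ratio, it was 0.487, below it. TAGTAA was then set against matched windows, where its ratio was 1.21. That of TTAAAA was 1.15 there (interval 1.08 to 1.22), and it was called higher in 2 of the 20 draws. In the draws 117 to 176 of 2081 motifs had an unadjusted exact-test p below 0.05, so smaller differences beyond composition may remain. The 2.05-fold excess of ACAGTG over windows of equal G+C stays open, and what binds there was not tested.

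A preference of the libraries for A+T-rich DNA may contribute, because G+C decreased by 5.70 points even at ranks 20001 to 30000, against 0.0452 at random positions; weak real binding in A+T-rich DNA stays open.

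Gene length was weighed for the list calls. Of the 4 lists called higher without length matching, 25%, the ribosomal proteins, were called higher with it, in a planned test whose outcome lay between the bounds set for it. The ribosomal proteins, with a median locus of 2.33 kb, went from 2.51 times the expected number without matching to 3.69 times with it, so that matching on length did not lower their ratio. The EGFR, trachea and ecdysone lists went from 4.39, 5.33 and 3.80 times the expected number without matching to 2.48, 2.70 and 1.81 times with it. None of them was called with matching in the main setting, where their unadjusted permutation p values were 0.021, 0.0086 and 0.173. For these 13, 11 and 13 genes the excess over length-matched genes cannot be told apart there from chance over the 27 lists. With matching, the trachea list was called only when genes were assigned by nearest start (ratio 3.29, adjusted permutation p = 0.025).

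Peaks with a homeodomain site within 50 bp of the summit did not differ detectably in signal in the planned test. The median signal was 111.7 for 468 peaks with a site and 110.1 for 1127 without, a ratio of 1.02 (bootstrap interval 0.965 to 1.07, permutation p = 0.558).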
